A study of Arabidopsis thaliana with 30 samples.

How the data were processed

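RNA sequencing libraries of whole Arabidopsis thaliana seedlings were compared by genotype and by DNA-damaging treatment. Seedlings of the wild type Col-0 and of a mutant named Δlinda were 14 days old and grown under 10 h of light per day, per the labels' protocols. They were exposed to 80 µg/ml Zeocin, a bleomycin-type drug that breaks both DNA strands, in liquid medium, with mock-treated seedlings as the control. Other seedlings received 2 kJ UV-C, which mainly forms pyrimidine dimers, with seedlings left in normal light as the control. Mock, Zeocin and UV-C seedlings were harvested at 3 h, and the labels give no time for those in normal light. Per the labels' protocols, RNA was isolated with a Quick-RNA Plant kit and a sequencing company built the libraries by random fragmentation and adapter ligation; no strand setting is given there.

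Samples were grouped by title into 8 groups and 30 libraries: mock Col-0 (n = 4), mock Δlinda (n = 3), Zeocin Col-0 (n = 3), Zeocin Δlinda (n = 4), and 4 libraries each for normal light and UV-C in Col-0 and Δlinda. The series design text gives 4 samples in every group, so 2 groups of 3 hold fewer than it states. The library mock Col-0 replicate 1 carries Col-0 in its title, description and column name and delta_linda in its genotype tag; it was grouped by its title. The treatment protocol attaches the word mock to the liquid medium with Zeocin, against the titles and the design text; the groups follow the titles.

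Reads were trimmed with Trimmomatic 0.38.0, checked with FastQC 0.72 and quantified with Salmon 0.14.1.2, per the submitters' processing notes, which give neither the transcript set nor the genome build. The deposited table holds estimated counts per gene, not normalised, for 68575 identifiers. In it the decimal mark of every estimate that was not whole is missing, so that an estimate with 3 decimals stands 1000-fold too high. This was read from the values and is stated in no label. The mark was put back by choosing, per gene and over all libraries together, the placement of 0 to 3 decimals that gave the best joint likelihood, with replicates of a group sharing a level under a t-tailed spread of the log count and groups sharing a looser gene level. Of 723692 entries above 0, 107354 (14.83%) received decimals: 811 received 1, 7142 received 2 and 99401 received 3. A gene was left out where the placement was unclear in any library. This removed 3368 genes and left 65207; among 20818 genes with a mean of 10 counts or more, 1683 (8.1%) were removed. Neighbouring loci that share reads, 199 pairs, were picked by entries with 3 restored decimals that add up to a whole number within 0.002. Of the pairs' 500 entries with 1 or 2 decimals, which were not used to pick them, 477 did so. On simulated data of 22294 genes, 6 kept genes (0.028%) held a wrongly read entry. There 3.69% of all simulated genes were left out as unclear, against the 8.1% of real genes with a mean of 10 counts or more. The simulated data may thus be easier to read, and the real share of wrong entries may be higher. Since the placement uses the groups and a shared gene level, it can draw replicates or groups together, so the spread within groups and changes between them may be understated for genes with restored decimals. Without the groups 160 entries in 45 genes, of 62253 genes clear both ways, were read differently.

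Restored totals were between 13.07 M and 15.34 M counts in 29 libraries and 8.07 M in normal light Δlinda replicate 1. Restored counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. All 30 libraries entered 1 fit with 1 coefficient per group; genes were filtered by filterByExpr (count 10, total count 15), which left 20544, libraries were scaled by TMM, and the quasi-likelihood F test with robust empirical Bayes was used. P-values were adjusted by the Benjamini-Hochberg method within each of 12 comparisons with a threshold of 0.05. Standard errors of log2 folds were taken as the absolute log2 fold divided by the square root of F. Levels are TMM-normalised CPM, given as mean ± SD over libraries. P-values measure the spread between samples only. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Where every library of a group had 0 counts, the fold is a lower bound against a floor of 3 counts per library; where a group held 1 to 3 counts in all, the ratio is given with an exact 95% counting interval.

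Of the 68575 identifiers, 37379 matched the TAIR10.1 gene table used as reference, as did 20330 of the 20544 tested; symbols come from that table. Since the build of the deposited table is not given in the sources used here, no coordinates are printed. The comparisons were the effect of each treatment in each genotype, the effect of genotype in each of the 4 conditions, both treatment by genotype interactions, the difference between the Zeocin and UV-C responses in Col-0, and mock against normal light in Col-0. The size of each response by genotype was compared with an exact two-sided permutation test that exchanges genotype labels within treated and within control libraries. It used genes past the threshold for the average response with an average change of at least 2-fold on mean log2 CPM (prior count 2).

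Gene lists numbered 23 with 352 genes, of which 315 were tested: double-strand break response, other repair and damage signalling, G2/M cell cycle, S phase and replication, UV and photomorphogenic response, oxidative stress, mitochondrial retrograde response, pattern-triggered immunity, salicylic acid defence, jasmonate, ethylene, abscisic acid, heat shock, unfolded protein response, cell death, autophagy, photosynthesis, circadian clock, auxin, cytokinin, and markers of root, stomatal and vascular cells. Unclear decimals removed, among others, 7 of 21 double-strand break, 6 of 21 photosynthesis and 3 of 14 pattern-triggered immunity genes. Counts of members leave these out. The lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a comparison. Each was also tested with a correlation estimated per list and with fry. Counts of members past the threshold are over all genes tested, and "adjusted over the list alone" where said. The lists, the comparisons, the tests, the other settings tried and the rule for named genes were fixed before the data were examined. Tests chosen later are named as such. The rule names the 10 largest rises and falls among genes past the threshold with an average log2 CPM of at least 1 and no overlap between the 2 groups' libraries. It adds up to 4 members per list with the smallest adjusted p, any member needed to state a count of 5 or fewer, and the LINDA gene with its nearest annotated neighbours. A gene outside this rule is named as chosen after its values were seen.

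The other settings were DESeq2 1.42.0 (Wald test), RLE size factors, no filter, a filter of CPM 1 in 4 libraries, a fit of only the groups compared, the replicate number as a block, edgeR without robust empirical Bayes, and each library left out in turn. Added after the data were seen were a fit that includes the genes with unclear decimals, a fit of only those genes read as whole in all libraries, and mock Col-0 replicate 1 grouped by its tag. Restoration used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and Numba 0.67.0, and figures were drawn with Matplotlib 3.10.9.

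All steps were tested on simulated counts with 200 changed genes per comparison, and all other genes were set to no effect. The real UV-C comparisons called 14221 genes in Col-0 and 14076 in Δlinda. The shares below therefore do not describe recovery where most genes change. At simulated folds of 1.5, 2 and 4, the edgeR step recovered 25.4%, 67.2% and 87.9% for Zeocin in Col-0, 16.4%, 62.7% and 86.4% for Zeocin in Δlinda, 25.4%, 71.6% and 75.8% for UV-C in Col-0, and 40.3%, 65.7% and 89.4% for UV-C in Δlinda. For the effect of genotype it recovered 23.9%, 68.7% and 93.9% in mock, 32.8%, 61.2% and 92.4% after Zeocin, 25.4%, 67.2% and 83.3% in normal light, and 32.8%, 70.1% and 84.8% after UV-C. For the interactions the shares were 6%, 28.4% and 84.8% (Zeocin) and 3%, 58.2% and 69.7% (UV-C); for Zeocin against UV-C in Col-0 they were 7.5%, 49.3% and 81.8%, and for mock against normal light 43.3%, 62.7% and 89.4%. Unchanged genes were called too. By edgeR they numbered 6 for Zeocin in Col-0, 10 for Zeocin in Δlinda, 12 for genotype after Zeocin and 5 for genotype in normal light. By DESeq2 they numbered 17, 20, 20 and 10 in the same order, so its larger counts can hold more false calls. A list made to change was called in all 12 comparisons and 0 of 22 unchanged lists was called in any. The simulated genes were drawn independently, so this does not test false list calls where members vary together. For the response size, a simulated response ratio of 0.7 (Δlinda to Col-0) gave a median difference of -0.522 (exact permutation p = 0.025) for Zeocin and -0.594 (p = 0.026) for UV-C, and a ratio of 1 gave -0.019 (p = 0.45) and 0.004 (p = 0.31).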

Results

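The libraries ask which transcripts of Arabidopsis seedlings change within 3 h of a drug that breaks DNA or of UV-C light, and whether a mutant of the long noncoding RNA LINDA differs from the wild type with or without that damage. Zeocin and mock libraries (3 to 4 per group, 14 in all) and UV-C and normal light libraries (4 per group, 16 in all) came from whole seedlings of Col-0 and Δlinda. Totals were 13.07 M to 15.34 M estimated counts, with 1 library at 8.07 M. Each treatment was compared with its own control in each genotype, genotypes were compared within each condition, and the interaction asks whether the genotypes respond differently. Values given as log2 are folds ± SE from edgeR, and adjusted p-values of single genes are from its quasi-likelihood test with Benjamini-Hochberg adjustment over 20544 genes.

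No table used here ties the name LINDA to a gene identifier. The noncoding gene AT3G00800 is taken as its locus from general knowledge of the study, and since the deleted part is not given in the sources used here, its level checks no genotype label. AT3G00800 had 0 to 13 counts per library in mock Col-0 and 0 to 5 in mock Δlinda, and 506 to 779 and 135 to 444 after Zeocin in Col-0 and Δlinda. In normal light it had 0 to 1 counts in Col-0 and 0 in Δlinda, and after UV-C 74 to 148 in Col-0 and 14 to 25 in Δlinda. Zeocin raised it from 0.393 ± 0.356 to 41.4 ± 8.31 CPM in Col-0 (log2 6.69 ± 0.47, edgeR adjusted p = 8.2e-11) and from 0.175 ± 0.165 to 18.7 ± 8.08 CPM in Δlinda (6.67 ± 0.59). UV-C raised it to 11.5 ± 3.66 CPM in Col-0 (n = 4), 494-fold over a control with 1 count in all (95% counting interval 88.2 to 19500). In Δlinda UV-C raised it to 1.91 ± 0.484 CPM (n = 4), at least 5.93-fold over a control at 0. After UV-C it was lower in Δlinda than in Col-0 (-2.59 ± 0.39, edgeR adjusted p = 0.0051; 0.066 without UV-C Δlinda replicate 1). After Zeocin the difference was -1.15 ± 0.33 (adjusted p = 0.14). The neighbour AT3G45730 rose with both treatments in both genotypes: 3.79 ± 0.32 (Zeocin, Col-0; 12.7 ± 6.61 to 176 ± 53.8 CPM), 4.93 ± 0.38 (Zeocin, Δlinda), 5.53 ± 0.36 (UV-C, Col-0) and 5.98 ± 0.38 (UV-C, Δlinda). The next gene on that side, AT3G45740, had values of -0.27 ± 0.13, -0.41 ± 0.13, 0.08 ± 0.13 and -0.07 ± 0.12 in the same order. AT3G45720 on the other side had 0 to 13 counts per library and was not tested.

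**Figure D1:**
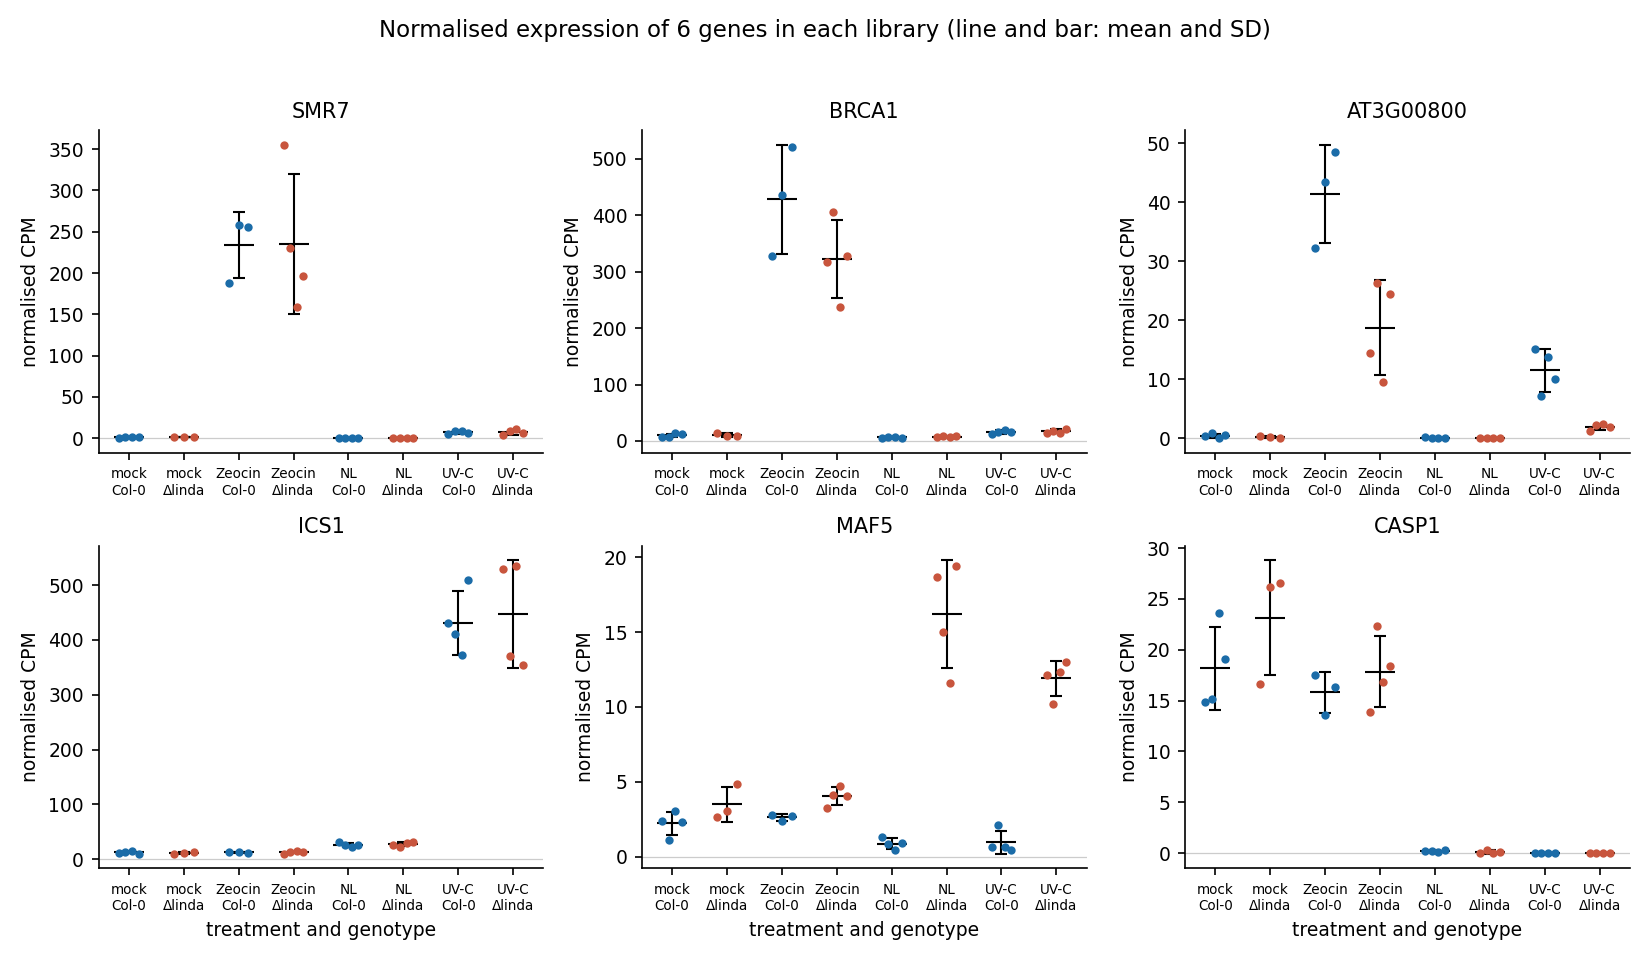
Normalised CPM (vertical axis, 1 point per library) of SMR7, BRCA1, AT3G00800, ICS1, MAF5 and CASP1 in the 8 groups of 3 or 4 libraries (blue Col-0, red Δlinda), with group means and SD as bars. SMR7 averaged 1.22 in mock Col-0 and 234 after Zeocin, and ICS1 26.3 in normal light and 431 after UV-C in Col-0.

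Zeocin raised the genes of the double-strand break response in Col-0. SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, rose from 1.22 ± 0.646 CPM in mock (n = 4) to 234 ± 40.2 CPM (n = 3, log2 7.56 ± 0.37, edgeR adjusted p = 1.6e-14). BRCA1 (AT4G21070), a recombination repair gene, rose from 10 ± 3 to 428 ± 95.9 CPM (5.41 ± 0.25), and SYN2 (AT5G40840), a cohesin subunit, from 6.85 ± 0.695 to 175 ± 28.2 CPM (4.67 ± 0.20). The mitotic cyclin CYCB1;1 (AT4G37490) rose by 3.76 ± 0.20 and the poly(ADP-ribose) polymerase PARP1 (AT2G31320) by 3.58 ± 0.19. Of the 21 genes of this list 7 were left out for unclear decimals. Of the 14 measured members 13 rose and 0 fell (median log2 4.31, camera adjusted p = 5.7e-137, and 2.5e-09 with an estimated correlation), and no left-out library changed the count. RNR1 (AT2G21790), the large subunit of ribonucleotide reductase, rose from 69.5 ± 3.98 to 376 ± 21.6 CPM (2.43 ± 0.16). Of the 16 other repair and signalling genes 2 rose, the translesion polymerase POLK (AT1G49980, 2.11 ± 0.13) and the end-joining ligase LIG4 (AT5G57160, 0.58 ± 0.12), and 0 fell (camera adjusted p = 0.0066; adjusted p = 0.32 with an estimated correlation). SOG1 (AT1G25580), the transcription factor of the plant damage response, had 0.30 ± 0.13 (edgeR adjusted p = 0.23). Among the largest rises were AT1G20750, 3320-fold over a control with few counts (95% counting interval 595 to 131000), the DNA methyltransferase gene DRM1 (AT5G15380), at least 42.2-fold higher, and DRP4C (AT1G60500), at least 32.5-fold higher. Others were AT4G25330 (7.77 ± 0.51), AT4G22960 (6.88 ± 0.29) and AT1G68200 (6.14 ± 0.38).

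Mitotic genes fell in the same Col-0 seedlings. Of 23 measured G2/M genes 9 fell and 0 rose, and 17 fell when adjusted over the list alone (median -0.71; camera adjusted p = 9.5e-09; adjusted p = 0.32 with an estimated correlation). The B-type cyclin CYCB1;2 (AT5G06150) fell from 18.9 ± 4.99 to 9.39 ± 4.08 CPM (-1.01 ± 0.23, edgeR adjusted p = 0.006; 0.059 without Zeocin Col-0 replicate 2 and 0.099 without replicate 3). The count of 9 rests on single libraries: it was 4, 1, 3 and 15 without mock Col-0 replicates 1 to 4, 1 without Zeocin Col-0 replicate 2 and 0 without replicate 3. Of 19 S-phase genes 1 rose (RNR1) and 2 fell, MCM7 (AT4G02060, -0.76) and CDT1A (AT2G31270, -0.75 ± 0.18), and 8 fell when adjusted over the list alone (camera adjusted p = 0.015; adjusted p = 0.55 with an estimated correlation). The falls numbered 0 without mock Col-0 replicate 3 and 5 without Zeocin Col-0 replicate 1. Other falls were the peroxidase gene AT2G41480 (-1.78 ± 0.32), AT2G44580 (-1.38 ± 0.24), AT4G28310 (-1.37 ± 0.26) and the clock gene RVE1 (AT5G17300, -1.09 ± 0.18).

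Zeocin also changed genes of stress and defence in Col-0. SAG101 (AT5G14930) and EDS1 (AT3G48090), lipase-like partners in immunity, rose by 2.43 ± 0.16 and 0.83 ± 0.13, as 2 of 14 salicylic acid genes (camera adjusted p = 0.00025; adjusted p = 0.32 with an estimated correlation). OM66 (AT3G50930), a protein of the outer mitochondrial membrane, rose by 2.33 ± 0.29 and NDA2 (AT2G29990) by 0.84 ± 0.21, as 2 of 8 mitochondrial retrograde genes (camera adjusted p = 0.0064; adjusted p = 0.32 with an estimated correlation). Of these 1 rose without Zeocin Col-0 replicate 2. Of 11 genes of pattern-triggered immunity 4 rose, and 7 when adjusted over the list alone (camera adjusted p = 0.0041; adjusted p = 0.32 with an estimated correlation). That 4 was 1 without mock Col-0 replicate 1 or 2 or Zeocin Col-0 replicate 2 or 3, and 2 without mock Col-0 replicate 3 or 4. The autophagy receptor NBR1 (AT4G24690) rose by 1.04 ± 0.12, as 1 of 3 rises among 15 autophagy genes (camera adjusted p = 0.015; adjusted p = 0.55 with an estimated correlation). The rises numbered 1 without Zeocin Col-0 replicate 2 and 5 without replicate 1. Among 14 oxidative stress genes 3 rose (1 without Zeocin Col-0 replicate 2), the kinase OXI1 (AT3G25250) by 3.44 ± 0.31. NAC103 (AT5G64060), a transcription factor counted in the unfolded protein list, rose by 4.90 ± 0.23 as 1 of 2 among 12. Single rises were AOC1 (AT3G25760) of 19 jasmonate genes (1.26 ± 0.28), the sieve-element gene SEOR1 (AT3G01680) of 8 vascular markers (0.87 ± 0.12) and 1 of 17 cell death genes. IAA5 (AT1G15580, 3.58 ± 0.53) was 1 of 2 among 12 auxin genes, of which 1 fell. Falls numbered 1 of 17 abscisic acid genes (3 adjusted over the list alone; camera adjusted p = 0.0091, adjusted p = 0.55 with an estimated correlation), 1 of 12 heat shock genes and 2 of 15 clock genes. No gene of the ethylene (12; 3 rose without Zeocin Col-0 replicate 1), photosynthesis (15), UV and photomorphogenic (19), cytokinin (5), root (13) or stomatal (5) lists passed by edgeR. In all 1115 of 20544 genes changed (819 up, 296 down, 1336 by DESeq2; 672 without Zeocin Col-0 replicate 2 and 731 without replicate 3).

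The Δlinda seedlings raised the same double-strand break list after Zeocin. SMR7 rose from 1.13 ± 0.305 CPM (n = 3) to 235 ± 85.2 CPM (n = 4, 7.69 ± 0.42), BRCA1 from 11.2 ± 3.39 to 322 ± 69.1 CPM (4.85 ± 0.27), SYN2 by 4.14 ± 0.21 and the checkpoint gene RAD17 (AT5G66130) by 3.62 ± 0.22. Of the 14 members 13 rose (median 3.99; camera adjusted p = 1.5e-132, and 2.2e-09 with an estimated correlation). The fall of BARD1 (AT1G04020), a partner of BRCA1 (-0.81 ± 0.20, edgeR adjusted p = 0.02), had adjusted p = 0.18 and 0.084 without mock Δlinda replicates 1 and 3, and 0.1, 0.072 and 0.083 without Zeocin Δlinda replicates 1, 2 and 4. POLK (1.83 ± 0.14) and LIG4 (0.58 ± 0.13) were again the 2 rises of 16 other repair genes, and RNR1 rose by 2.2 ± 0.17. NAC103 (4.77 ± 0.26), IAA5 (3.52 ± 0.54), OXI1 (3.34 ± 0.34), SAG101 (1.98 ± 0.17) and NBR1 (0.82 ± 0.12) rose too. AT2G37960 (-2.12 ± 0.36), AT2G44580 (-1.87 ± 0.23), AT1G16630 (-1.51 ± 0.28) and AT2G41480 (-1.49 ± 0.30) fell. Of 23 G2/M genes 6 fell, and 14 adjusted over the list alone (camera adjusted p = 5.1e-11; adjusted p = 0.38 with an estimated correlation). That count was 2 without mock Δlinda replicate 1 and 1 without mock Δlinda replicate 2 or 3 or Zeocin Δlinda replicate 1 or 4. S-phase genes fell in 3 of 19, and 13 adjusted over the list alone (camera adjusted p = 0.00036; adjusted p = 0.52 with an estimated correlation). It was 0 without mock Δlinda replicate 1 and 5 without Zeocin Δlinda replicate 3. The mitochondrial retrograde list was called with 1 rise of 8 (camera adjusted p = 0.0038; adjusted p = 0.46 with an estimated correlation). The unfolded protein (0.04), autophagy (0.037) and root marker (0.03) lists were called too, with adjusted p = 0.63, 0.63 and 0.52 with an estimated correlation. No root marker passed by edgeR singly. In all 583 genes changed (480 up, 103 down, 771 by DESeq2). The genotypes shared 422 rises and 50 falls (19.1 and 1.48 for independent lists) with 0 in opposite directions (11).

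Most transcripts of Col-0 differed between seedlings 3 h after UV-C and seedlings in normal light. No harvest time is given for the latter, so a difference in harvest time cannot be told apart from the effect of UV-C. OM66 rose from 4.29 ± 1.53 CPM in normal light to 641 ± 28.2 CPM (n = 4 each, 7.23 ± 0.33). ICS1 (AT1G74710), the isochorismate synthase of salicylic acid synthesis, rose from 26.3 ± 3.42 to 431 ± 57.7 CPM (4.03 ± 0.16), and ACS6 (AT4G11280), an ethylene synthesis enzyme, from 11.4 ± 2.37 to 648 ± 39.1 CPM (5.82 ± 0.23). BZIP60 (AT1G42990), a transcription factor of the unfolded protein response, rose from 19.9 ± 2.06 to 546 ± 24.9 CPM (4.78 ± 0.18). The wall-loosening expansin EXPA8 (AT2G40610) fell from 252 ± 36 to 2.67 ± 0.883 CPM (-6.56 ± 0.44) and GASA6 (AT1G74670) by 6.14 ± 0.34 on the log2 scale. Of 20544 genes 7454 rose and 6767 fell (14221, 14332 by DESeq2). AT3G41768, a ribosomal RNA gene in the reference, and AT3G06365, a miscellaneous RNA gene there, together held 11.6 ± 1.1% of all counts here against 1.12 ± 0.35% in normal light. Chloroplast-encoded genes held 1.595% to 3.051% over the 8 UV-C libraries of both genotypes against 0.09% to 1.474% in the others. Folds are relative to the remaining genes.

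Immunity, salicylic acid, ethylene and mitochondrial retrograde genes rose as whole lists after UV-C in Col-0. All 11 measured genes of pattern-triggered immunity rose, with the kinase MPK11 (AT1G01560) at 6.68 ± 0.36 and PROPEP3 (AT5G64905), an immune peptide precursor, at least 127-fold higher (list median 6.51, or 5.68 with genes at their bound; adjusted p = 0.018 with an estimated correlation). So did 14 of 14 salicylic acid genes, with EDS1 at 3.79 ± 0.13 and the transporter EDS5 (AT4G39030) at 5.76 ± 0.26 (0.018). Of 12 ethylene genes 12 rose, with ACS2 (AT1G01480) at 10.69 ± 0.38 and ERF11 (AT1G28370) at 7.37 ± 0.41 (0.034). All 8 mitochondrial retrograde genes rose, the alternative NADH dehydrogenase NDB2 (AT4G05020) by 5.80 ± 0.25 and the regulator NAC017 (AT1G34190) by 1.49 ± 0.10 (adjusted p = 0.034 with an estimated correlation). Every one of 12 unfolded protein genes rose, the cochaperone ERDJ3A (AT3G08970) by 4.01 ± 0.24, with adjusted p = 0.11 with an estimated correlation. The near-identical BIP1 (AT5G28540) and BIP2 (AT5G42020) share reads and are uncertain singly. Jasmonate genes rose in 16 and fell in 3 of 19 (0 without normal light Col-0 replicate 1). The repressors JAZ1 (AT1G19180) and JAZ5 (AT1G17380) rose by 6.42 ± 0.24 and 7.21 ± 0.29 (list median 2.48, 2.16 at the bound; adjusted p = 0.24 with an estimated correlation). Oxidative stress genes rose in 10 and fell in 4 of 14, with OXI1 at 8.90 ± 0.48, the zinc finger gene ZAT10 (AT1G27730) at 7.83 ± 0.45 and the NADPH oxidase RBOHD (AT5G47910) at 2.76 ± 0.18 (adjusted p = 0.24 with an estimated correlation).

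**Figure D2:**
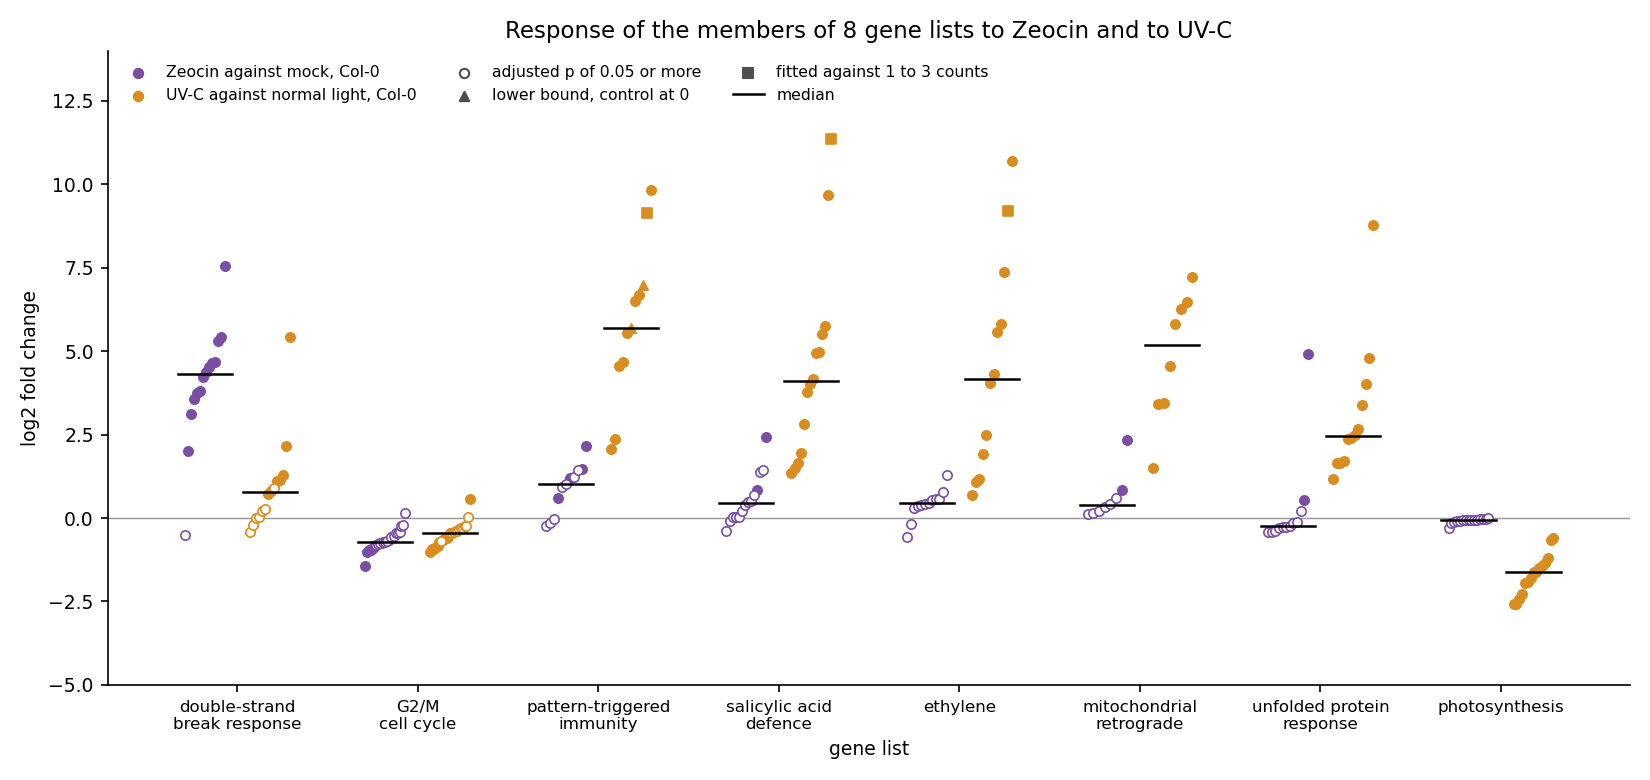
Log2 folds (vertical axis) of the measured members of 8 gene lists in Col-0 after Zeocin (purple, n = 3 against 4) and UV-C (orange, n = 4 against 4). Open points did not pass an adjusted p of 0.05, triangles are lower bounds with the control at 0, squares are fitted against 1 to 3 control counts, and black lines are medians, 4.31 for the double-strand break response after Zeocin and 0.77 after UV-C.

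Photosynthesis genes and stomatal markers fell after UV-C in Col-0. GLK2 (AT5G44190), a regulator of chloroplast development, fell by 2.58 ± 0.13 and LHCB4.2 (AT3G08940), a light-harvesting protein, by 2.27 ± 0.20 on the log2 scale, as did 15 of 15 photosynthesis genes (median -1.63; adjusted p = 0.30 with an estimated correlation). LHCB2.1 (AT2G05100) fell from 7980 ± 606 to 1490 ± 74.4 CPM, but shares reads with LHCB2.2 (AT2G05070) and is uncertain singly. All 5 stomatal lineage markers fell, among them TMM (AT1G80080, -2.07 ± 0.17) and SPCH (AT5G53210, -1.69 ± 0.24; adjusted p = 0.24 with an estimated correlation). Auxin genes fell in 6 and rose in 3 of 12, the efflux carriers PIN7 (AT1G23080) and PIN3 (AT1G70940) by 3.80 ± 0.22 and 2.50 ± 0.21 on the log2 scale. Cytokinin response genes fell in 3 and rose in 1 of 5, with ARR16 (AT2G40670) at -3.38 ± 0.37. Clock genes rose in 5 and fell in 9 of 15, with LHY (AT1G01060) at 3.5 ± 0.24 and CHE (AT5G08330) at -2.17 ± 0.17. Of 23 G2/M genes 10 fell and 1 rose, with the kinases AUR1 (AT4G32830) at -1.03 ± 0.20 and CDKB2;1 (AT1G76540) at -0.85 ± 0.17. S-phase genes rose in 2 and fell in 3 of 19.

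The double-strand break list was not called as a whole after UV-C in Col-0. Of 14 members 7 rose and 0 fell (median 0.77; camera adjusted p = 0.36), with SMR7 going from 0.164 ± 0.052 to 7.26 ± 1.86 CPM (5.41 ± 0.59), AGO2 (AT1G31280) at 2.15 ± 0.18 and BRCA1 at 1.3 ± 0.24. Other repair genes rose in 4 and fell in 5 of 16 (3 without normal light replicate 2 or UV-C replicate 1). SOG1 rose by 1.52 ± 0.12 and the end-binding subunit KU70 (AT1G16970) by 0.81 ± 0.11, and the UV lesion polymerase POLH (AT5G44740) fell by 0.74 ± 0.16 on the log2 scale. UV and photomorphogenic genes rose in 6 and fell in 4 of 19. ELIP2 (AT4G14690) and HYH (AT3G17609) rose by 5.75 ± 0.54 and 2.43 ± 0.21, and the UV-B receptor UVR8 (AT5G63860) had -0.95 ± 0.09. Heat shock genes rose in 7 of 12 and fell in 0, with HSP90.1 (AT5G52640) at 7.12 ± 0.43 and HSP70 (AT3G12580) at 6.14 ± 0.40. Cell death genes rose in 10 and fell in 3 of 17. The metacaspases MC1 (AT1G02170) and MC8 (AT1G16420) rose by 2.70 ± 0.14 and 7.80 ± 0.59, and so did the death suppressor BI1 (AT5G47120, 2.30 ± 0.14). Autophagy genes rose in 9 and fell in 2 of 15. Abscisic acid genes rose in 7 and fell in 6 of 17 (3 falls without normal light replicate 4 or UV-C replicate 2). Root markers rose in 1 and fell in 3 of 13, and vascular markers 2 and 1 of 8 (5 rises without normal light replicate 2).

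Most transcripts of Δlinda differed between UV-C and normal light as well, with the same limit on harvest time. EDS1 rose by 3.81 ± 0.13, ICS1 by 4.01 ± 0.16, ACS2 by 10.43 ± 0.39, JAZ1 by 6.35 ± 0.24, NDB2 by 5.44 ± 0.24, OM66 by 6.75 ± 0.33 and BZIP60 by 4.79 ± 0.18 (n = 4 each). GLK2 fell by 2.57 ± 0.13, PIN7 by 3.3 ± 0.22, EXPA8 by 5.91 ± 0.43 and TMM by 2.2 ± 0.17 on the log2 scale. All members rose of the immunity (11; median 5.22), salicylic acid (14), ethylene (12) and mitochondrial retrograde (8) lists, with adjusted p = 0.023, 0.023, 0.043 and 0.041 with an estimated correlation, and of the unfolded protein list (12; 0.081). All 15 photosynthesis and 5 stomatal genes fell (adjusted p = 0.36 and 0.18 with an estimated correlation). Jasmonate genes rose in 15 and fell in 0 of 19, oxidative stress genes 8 and 3 of 14, heat shock genes 8 and 0 of 12, and G2/M genes 0 and 18 of 23 (adjusted p = 0.25, 0.34, 0.49 and 0.72 with an estimated correlation). The mitotic gene MAP65-3 (AT5G51600) fell by 1.25 ± 0.20 on the log2 scale. Rises and falls were 6 and 2 of 14 in the double-strand break list (1 fall without normal light Δlinda replicate 1), 5 and 5 of 16 other repair genes, 2 and 5 of 19 S-phase genes (2 falls without normal light Δlinda replicate 2). They were 6 and 9 of 19 photomorphogenic, 13 and 3 of 17 cell death, 10 and 1 of 15 autophagy and 8 and 3 of 17 abscisic acid (5 falls without normal light Δlinda replicate 4). Clock genes had 3 and 7 of 15, with 3 and 6 of 12 auxin, 1 and 3 of 5 cytokinin, 0 and 3 of 13 root and 2 and 1 of 8 vascular genes. In all 14076 genes changed (7427 up, 6649 down, 14191 by DESeq2). Of these 6630 rises and 5965 falls were shared with Col-0 (2690 and 2190 for independent lists) and 4 were opposite (4860). AT3G41768 and AT3G06365 together held 7.73 ± 1.8% of counts here, below UV-C Col-0 (exact two-sided permutation p = 0.029, the smallest possible; adjusted p = 0.039 over 4 tests), and 0.845 ± 0.2% in normal light. The test of this share was chosen after its values were seen.

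Untreated seedlings of the genotypes in mock showed no gene past the threshold by edgeR, with 767 at an unadjusted p under 0.05 and 0 by DESeq2. Lists were called for jasmonate (higher in Δlinda, camera adjusted p = 2.1e-06), clock (lower, 0.002), unfolded protein (higher, 0.0046) and autophagy (lower, 0.045) genes, with adjusted p = 0.45, 0.45, 0.86 and 0.89 with an estimated correlation. Fry called 0 lists here, in every other comparison of the genotypes below and in both interactions.

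After Zeocin 31 genes were lower and 2 higher in Δlinda than in Col-0 (n = 4 against 3). EBF2 (AT5G25350), an F-box protein of ethylene signalling, went from 93.7 ± 25.1 to 42.8 ± 16 CPM (-1.13 ± 0.20). Also lower were the ethylene receptor ETR2 (AT3G23150, -1.35 ± 0.28), SAG101 (-0.86 ± 0.16), the flagellin receptor FLS2 (AT5G46330, -1.62 ± 0.31) and AT5G22520 (-2.43 ± 0.43). AT4G39795 (1.65 ± 0.36) and AT3G20015 (0.99 ± 0.20) were higher. The light-signalling factor PIF3 (AT1G09530, -1.43 ± 0.26, edgeR adjusted p = 0.02) was chosen after its values were seen. BRCA1 had -0.41 ± 0.21 and no double-strand break gene passed by edgeR (camera adjusted p = 0.0072 for lower, median -0.31; adjusted p = 0.6 with an estimated correlation). Of 12 ethylene genes 2 were lower, and 4 adjusted over the list alone (camera adjusted p = 0.0017; adjusted p = 0.56 with an estimated correlation). The count was 0 without Zeocin Col-0 replicate 2, and 4 without Zeocin Col-0 replicate 1 or Zeocin Δlinda replicate 4. Other called lists were abscisic acid, higher (1.9e-05; 8 of 17 adjusted over the list alone), unfolded protein (0.0017), photosynthesis (0.0042), photomorphogenic (0.024) and heat shock genes (0.029), all higher, and autophagy genes, lower (0.029), with adjusted p of 0.56 to 0.6 with an estimated correlation. The 33 calls rest on single libraries. By edgeR 781 (337 higher, 444 lower), 15 and 0 genes passed without Zeocin Col-0 replicates 1, 2 and 3, and 1, 18, 0 and 62 without Zeocin Δlinda replicates 1 to 4. DESeq2 called 231 (66 higher, 165 lower, 28.6% higher against 6.1% by edgeR).

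In normal light the floral repressors MAF5 (AT5G65080) and MAF4 (AT5G65070) were higher in Δlinda. MAF5 went from 0.866 ± 0.37 CPM in Col-0 to 16.2 ± 3.63 CPM (n = 4 each, 4.22 ± 0.34, edgeR adjusted p = 3.4e-09). MAF4 went from 3.75 ± 1.05 to 8.4 ± 1.17 CPM (1.17 ± 0.21, adjusted p = 0.0099; 0.09 without normal light Col-0 replicate 4 and 0.072 without normal light Δlinda replicate 4). These neighbours belong to a cluster of similar genes and can share reads. Lower were the defence regulators WRKY70 (AT3G56400, -1.83 ± 0.34), DMR6 (AT5G24530, -1.81 ± 0.30) and NDR1 (AT3G20600, -1.20 ± 0.20), and RAB18 (AT5G66400, -1.10 ± 0.21), a dehydrin of the abscisic acid response. Abscisic acid genes were lower as a list (1 of 17 passed and 9 adjusted over the list alone; camera adjusted p = 7.1e-14; adjusted p = 0.15 with an estimated correlation). Salicylic acid genes were lower too (1 of 14, and 5 alone, camera adjusted p = 1.9e-05; adjusted p = 0.29 with an estimated correlation), and G2/M (median 0.37) and immunity genes (median 1.09, or 0.44 with genes at their bound) were called as higher lists (1.6e-07 and 0.0052; adjusted p = 0.3 each with an estimated correlation). In these 0 of 23 and 0 of 11 genes passed by edgeR (0 and 1 adjusted over the list alone). Called with 0 genes by edgeR were also autophagy, photosynthesis and clock genes, lower (0.015 each), and S-phase (0.018), oxidative stress (0.022) and photomorphogenic genes (0.027), higher, with adjusted p from 0.3 to 0.58 with an estimated correlation. In all 31 genes passed (12 higher, 19 lower, 140 by DESeq2). There were 14, 64 and 2 without normal light Col-0 replicates 1, 2 and 4, and 73, 20 and 1 without normal light Δlinda replicates 1, 2 and 4. Of the named genes MAF5 passed without any one of the 8.

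After UV-C 3 genes differed by genotype. MAF5 was higher in Δlinda (0.962 ± 0.763 to 11.9 ± 1.2 CPM, n = 4 each; 3.61 ± 0.33, edgeR adjusted p = 1.3e-07), as was MAF4 (1.72 ± 0.446 to 8.3 ± 1.74 CPM, 2.27 ± 0.23), and AT3G00800 was lower. Abscisic acid (lower, camera adjusted p = 0.00014), unfolded protein (higher, 0.0027) and clock genes (0.013) were called as lists with 0 genes past the threshold by edgeR and adjusted p = 0.8 each with an estimated correlation. DESeq2 called 7 genes (28.6% higher against 66.7% by edgeR), and 5 passed without UV-C Δlinda replicate 4. The same groups differed in the share of counts on AT3G41768 and AT3G06365 (11.6% in Col-0 and 7.73% in Δlinda).

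No gene passed the Zeocin by genotype interaction by edgeR (smallest adjusted p = 0.685, 770 at an unadjusted p under 0.05, 0 by DESeq2, 1 without Zeocin Col-0 replicate 2). The UV-C by genotype interaction had none either by edgeR (smallest adjusted p = 0.0832, 1511 at an unadjusted p under 0.05, 19 by DESeq2, 10 without normal light Col-0 replicate 2). The median Zeocin response was 1.60 log2 units in Col-0 and 1.41 in Δlinda over 523 genes, with a median difference per gene of -0.203 (exact two-sided permutation p = 0.22 over 1225 relabellings). Of these genes 27.2% responded more in Δlinda. By the same exact test this median difference was -0.386 (p = 0.09) without Zeocin Col-0 replicate 1 and -0.1 without Zeocin Δlinda replicate 3. For UV-C it was 1.72 and 1.68 over 8289 genes, with a median difference per gene of -0.04 (exact two-sided permutation p = 0.46 over 4900). Double-strand break and ethylene genes were called for the Zeocin interaction (camera adjusted p = 0.0018 and 0.00083), with abscisic acid (7.9e-07), jasmonate (0.00032), photomorphogenic (0.0021), heat shock (0.0022), salicylic acid (0.0042) and immunity genes (0.0052). All had adjusted p = 0.31 with an estimated correlation. For UV-C salicylic acid (0.00055), photosynthesis (0.0013), immunity, photomorphogenic and oxidative stress (0.0032 each), autophagy (0.0044), abscisic acid (0.0067) and G2/M genes (0.029) were called, with adjusted p between 0.25 and 0.93 with an estimated correlation.

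The Zeocin and UV-C responses of Col-0 differed in many genes, among them double-strand break and defence genes. The Zeocin response exceeded the UV-C response at BRCA1 by 4.12 ± 0.33, SYN2 by 3.86 ± 0.30, RAD17 by 3.82 ± 0.29, PARP1 by 3.80 ± 0.26 and RNR1 by 2.37 ± 0.21, and in 12 of 14 members of the list (0 lower; adjusted p = 0.03 with an estimated correlation). It lay below the UV-C response at ACS2 (-10.87 ± 0.52), JAZ1 (-6.28 ± 0.31), NDB2 (-5.38 ± 0.33), BZIP60 (-4.24 ± 0.24), ICS1 (-4.02 ± 0.23) and SOG1 (-1.22 ± 0.18). The lower side held 8 of 8 mitochondrial retrograde, 11 of 11 immunity, 13 of 14 salicylic acid and 10 of 12 ethylene genes (adjusted p = 0.03 each with an estimated correlation). It also held 11 of 12 unfolded protein genes (0.075), 15 of 19 jasmonate (0.19), 9 of 14 oxidative stress (0.12) and 7 of 12 heat shock genes (adjusted p = 0.3 with an estimated correlation). NAC103, the unfolded protein gene on the other side, had 2.41 ± 0.43. Photosynthesis genes had the higher value after Zeocin in 15 of 15 and stomatal markers in 4 of 5 (adjusted p = 0.28 and 0.19 with an estimated correlation), with GLK2 at 2.26 ± 0.19 and PIN7 at 3.92 ± 0.30. AT3G45730 had -1.74 ± 0.47 (edgeR adjusted p = 0.0026). AT3G00800 had -1.76 ± 1.5 (edgeR adjusted p = 0.33), fitted against a normal light control with 1 count in all and thus uncertain. In all 11461 genes differed (5435 higher, 6026 lower, 11803 by DESeq2). Of the calls 521 rises and 203 falls were shared (297 and 97.5 for independent lists) and 141 genes were opposite (377). The controls of the experiments differed as well, in 11411 genes.

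The controls of the experiments differed in Col-0. CASP1 (AT2G36100), a protein of the root endodermis, had 0.186 ± 0.074 CPM in normal light and was higher by 6.55 ± 0.36 in mock (n = 4 each). Of 13 root markers 12 were higher in mock (median 6.55, 4.17 with genes at their bound; adjusted p = 0.011 with an estimated correlation). The root markers EXPA7 (AT1G12560), RHD6 (AT1G66470), PLT1 (AT3G20840) and PLT2 (AT1G51190), 4 of the 13, had 0 counts in all normal light libraries. The normal light mean was 80.8% of mock for SHR (AT4G37650), 61.5% for SCR (AT3G54220), 51% for ESB1 (AT2G28670) and 22.4% for WOX5 (AT3G11260). Photomorphogenic genes were higher in mock in 16 and lower in 1 of 19, with MYB12 (AT2G47460) at 4.30 ± 0.31 and HY5 (AT5G11260) at 2.52 ± 0.20 (adjusted p = 0.0098 with an estimated correlation). Photosynthesis genes were lower in mock in 15 of 15, with LHCB4.2 at -2.58 ± 0.20 and GLK1 (AT2G20570) at -2.40 ± 0.21 (adjusted p = 0.17 with an estimated correlation), beside the root marker values above. Stress genes were higher in mock in 10 of 12 for heat shock, 10 of 12 for ethylene and 11 of 14 for oxidative stress (camera adjusted p = 0.049, 0.047 and 0.038; adjusted p = 0.87, 0.87 and 0.64 with an estimated correlation), with OXI1 at 5.16 ± 0.55 and HSP70 at 2.87 ± 0.37. In all 11411 genes differed (6569 higher, 4842 lower, 11559 by DESeq2).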

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

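Apart from the test of a wrong label for Zeocin Col-0 replicate 1, every test below was chosen after its result was seen. An outlying library was looked for in 72 groups of 4 values, and 3 had one, where chance gives about 1 in 20.

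Normal light Δlinda replicate 1 lay apart from its group in depth, at 8.07 M counts (gap over range 0.845). MAF5 in UV-C Col-0 replicate 2 lay apart at 2.1 CPM (0.882). AT3G00800 in normal light Col-0 replicate 1 lay apart at 0.0953 CPM, which is 1 count where the others have 0. AT3G41768 and AT3G06365, outside the genes the comparisons speak of, together held 11.6% of counts in UV-C Col-0 and 7.73% in UV-C Δlinda, above the 1.12% and 0.845% of normal light.

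On mean log2 CPM the MAF5 genotype effect was larger by 3.39 in normal light than in mock and by 3.04 after UV-C than after Zeocin, and the MAF4 effect by 1.07 and 2.09; exact permutation picked out these differences in genes chosen for their effect in the UV-C experiment, and edgeR over all 20544 genes gave adjusted p = 0.00038, 0.0035, 0.42 and 0.0017. For MAF5 dilution of shoot transcripts by root RNA was examined at a shoot share of 26% in mock. This share is the lowest ratio of mock to normal light given by the medians of the photosynthesis and stomatal lists. Dilution alone would then need a MAF5 difference of 3.98 CPM in mock. The measured one was 1.27 ± 0.79 CPM (SE), or 2.85 with 2 SE added. This argues against dilution as the whole cause at that share and leaves a lower share open. After UV-C the summed change of the similar MAF2, MAF3 and FLM was 11.4 ± 4.25 CPM (SE) beside a rise of 17.5 CPM for MAF5 and MAF4. This argues against reads moved away from MAF2, MAF3 and FLM as the whole cause there, since such a move would lower their sum. Reads shared from a rise of those genes stay open, since their sum rose too. In normal light, with -0.404 ± 6.94 CPM beside 20 CPM, moved reads stay open as well. Labels exchanged within the mock or Zeocin libraries would need a MAF5 difference of 3.03 CPM at the 26% share after subtracting 2 SE. The largest difference of any grouping was 2.41 CPM in mock and 1.52 CPM after Zeocin, which argues against such an exchange. Regrouping cannot show a genotype label that is wrong for a whole group, so wrong labels of that kind stay open. A biological difference, such as a genotype effect that depends on growth condition or a difference between seed stocks, stays open and was not tested.

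The number of genotype calls after Zeocin turns on Zeocin Col-0 replicate 1, with 33 genes with it and 781 without it. At 780 of those genes its median position was 0.17, where 0 is the Δlinda mean and 1 the mean of the other Col-0 libraries. A low position goes with a larger count without a library, so it cannot decide on a wrong genotype label, which stays open. Zeocin Δlinda replicate 4, with 62 genes without it, lay at 0.53, where 1 is the mean of its own group's other libraries. A weaker Zeocin exposure of Zeocin Col-0 replicate 1 could account for the count. Its 14 double-strand break genes lay at a median of -0.56 log2 from the other Zeocin Col-0 libraries (SE of the mean over genes 0.09). Genes of 1 library are not independent replicates, so this SE does not measure the spread between libraries. The same value was not taken for the other Zeocin libraries. The tables do not choose between the 2 explanations, and no biological explanation was tested.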

How the results depend on the processing

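Every count of genes was run again under each other setting, of which the inclusion of genes with unclear decimals, the restriction to genes read as whole, and the grouping of mock Col-0 replicate 1 by its tag were added after the data were seen. The cause of changed counts was not tested unless stated. With DESeq2 the genotype counts were 231 after Zeocin (33 by edgeR), 140 in normal light (31) and 7 after UV-C (3), and the UV-C interaction had 19 (0). With only the groups compared in the fit, Zeocin in Col-0 had 585 genes (1115), genotype after Zeocin 0 and genotype in normal light 12. Without robust empirical Bayes genotype after Zeocin had 54. With the genes of unclear decimals included, genotype had 13 genes in mock (0), 77 after Zeocin, 52 in normal light and 11 after UV-C, and the interactions 22 (Zeocin) and 16 (UV-C). That setting moved the median of all genes by -0.123 for UV-C in Col-0 and 0.143 for Zeocin against UV-C. With only genes whole in all libraries, UV-C had 9301 genes in Col-0 (14221) and 9321 in Δlinda (14076), Zeocin against UV-C 7529 (11461), genotype after Zeocin 20, in normal light 20 and after UV-C 1, where by construction fewer genes are tested. Grouping mock Col-0 replicate 1 by its tag gave 872 and 822 genes for Zeocin in Col-0 and Δlinda. Replicate numbers were not used as pairs in the main fit. Same-numbered libraries of compared groups had correlations of deviations from -0.38 to 0.18. In the UV-C experiment 2 to 3 of 4 libraries per pair of groups matched best with their own number. Weak pairing is therefore not excluded there. The replicate number as a block moved genotype in normal light to 19 genes and no other count by more than 1.5 times. The list calls numbered 17 with an estimated correlation, 94 at the preset one, 79 with fry and 96 with the block. With fry 47 of the 94 lost the call and 32 other lists gained it. Fry called 0 lists for genotype in mock, after Zeocin, in normal light and after UV-C. The preset correlation gave 4, 8, 10 and 3 there. For the interactions of Zeocin and UV-C fry called 0 lists, against 8 each. Leaving out each library in turn gave 672 to 1492 genes for Zeocin in Col-0 (without Zeocin Col-0 replicates 2 and 1), 412 to 632 for Zeocin in Δlinda, 13613 to 13842 and 13491 to 13787 for UV-C in Col-0 and Δlinda, and 0 to 1 for genotype in mock. Genotype ranged from 0 to 781 after Zeocin (without Zeocin Col-0 replicates 3 and 1), 1 to 73 in normal light (without normal light Δlinda replicates 4 and 1) and 2 to 5 after UV-C (without UV-C Δlinda replicates 1 and 4). The interactions ranged from 0 to 1 (Zeocin, 1 without Zeocin Col-0 replicate 2) and 0 to 10 (UV-C, 10 without normal light Col-0 replicate 2), Zeocin against UV-C from 10692 to 11316, and mock against normal light from 10505 to 10913. Of 717 called values of named genes 180 lost the call under 1 or more settings, 75 of them outside leaving out a library or fitting the compared groups alone, and of 1420 such values and 276 list values 0 changed direction.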

Other observations

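Other strong changes were seen at genes not described above. After UV-C the alternative oxidase gene AOX1D (AT1G32350) was at least 1530-fold higher in Col-0 than in normal light (n = 4 each), the glutathione transferase gene GSTU3 (AT2G29470) at least 161-fold in Col-0 and 151-fold in Δlinda, and FMO1 (AT1G19250), a monooxygenase of systemic immunity, at least 560-fold in Δlinda. CYP710A1 (AT2G34500), a sterol desaturase gene, rose 7280-fold in Col-0 against a control with few counts (95% counting interval 1310 to 287000). The cyclin CYCP4;1 (AT2G44740) fell by 5.85 ± 0.34 on the log2 scale in Col-0. After Zeocin in Δlinda DRM1 was at least 35-fold, AT1G30170 at least 28-fold and DRP4C at least 14.5-fold higher, and AT1G20750 rose 1950-fold (350 to 77000). Across genes, which are not independent replicates, the responses of the genotypes correlated at 0.59 for Zeocin and 0.93 for UV-C over 20544 genes, and the Zeocin and UV-C responses in Col-0 at 0.28. Over the 1115 genes called for Zeocin in Col-0 the Zeocin responses of the genotypes correlated at 0.92, and the Zeocin and UV-C responses at 0.44.

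All tests in the paragraphs below were chosen after the results were seen. For each comparison the libraries were split in all other ways into groups of the same sizes, or in 100 drawn ways where there are more, and genes were counted again. Chance can be excluded where 1 of 35 splits, the real one, called as many genes: Zeocin in Col-0 (1115, next highest 617), Zeocin in Δlinda (583, next 382), UV-C in Col-0 (14221, next 8), UV-C in Δlinda (14076, next 2599) and mock against normal light (11411, next 19). For genotype in normal light it was also 1 of 35 (31, next 28, from exchanging normal light Col-0 replicate 2 with normal light Δlinda replicate 1), the smallest share possible. That margin is narrow beside counts of 1 and 2 without normal light Δlinda replicate 4 and normal light Col-0 replicate 4, so chance is not called unlikely there. Nor is it called unlikely for the number of genes by genotype after Zeocin (33, 5 of 35, highest other 285) or after UV-C (3, 2 of 35, highest other 3). Of those 3 genes MAF5 and MAF4 passed without any one of the 8 libraries. Where the real count is 0, every split calls as many by construction and the splits say nothing about chance. This holds for genotype in mock (0 genes by edgeR, 767 at an unadjusted p under 0.05, 0 by DESeq2, 35 of 35 splits, highest other 13) and for the interactions of Zeocin (0 genes by edgeR, 770 at an unadjusted p under 0.05, 0 by DESeq2, 100 of 100 drawn splits, highest other 836) and UV-C (0 genes by edgeR, 1511 at an unadjusted p under 0.05, 19 by DESeq2, 100 of 100, highest other 13). The splits with 285 and 836 genes point to a structure of the libraries, whose source was not tested. The one with 285 exchanges Zeocin Col-0 replicate 1 with Zeocin Δlinda replicate 2, and the one with 836 exchanges Zeocin Col-0 replicate 1 with Zeocin Δlinda replicate 4 and nearly reverses the genotypes in mock. For Zeocin against UV-C 6 of 100 drawn splits gave as many genes as the real 11461 (highest other 12456). All 6 keep normal light and UV-C libraries apart, as 7 of the drawn splits do, and the highest of the splits that mix them was 231.

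In Col-0 9 of 13 root markers had a normal light mean under 10% of the mock mean, and 4 had 0 counts in all 8 normal light libraries. Little or no root tissue in that material may account for these 9, while SHR, SCR, ESB1 and WOX5 kept 22.4% to 80.8% of mock. Dilution of shoot RNA by root RNA would lower photosynthesis and stomatal genes alike in mock. The stomatal median lay 1.56 log2 units above that of photosynthesis genes (-0.38, from -0.56 to 0.59, against -1.95, from -2.58 to -0.62). This argues against dilution as the whole cause of the lower photosynthesis transcripts. Stomatal values up to 0.59 cannot come from dilution alone, so a rise in mock that hides dilution is not excluded. The labels describe whole seedlings, and the growth conditions of the experiments may differ as well, which was not tested.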
